A study of Lytechinus variegatus with 19 samples.

How the data were processed

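The series holds droplet single-cell RNA sequencing of wild-type embryos of the green sea urchin *Lytechinus variegatus*, collected at Beaufort, North Carolina. Embryos were reared in artificial sea water, dissociated at hourly steps in calcium-free sea water with glycine and EDTA, fixed in methanol, rehydrated in saline-sodium citrate and made into 10x Genomics Single Cell 3' version 3 libraries, per the labels' protocols. There were 19 libraries from 18 time points between 2 and 24 hours post fertilisation, and only 24 hours had 2 libraries.

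For each library the authors deposited a table of whole-number counts of unique molecular identifiers (UMIs), with gene models in lines and cell barcodes in columns. Cell Ranger 3.0.1 and Seurat 3.1 are named in the submitters' processing notes; the genome build, the annotation, the counting of reads shared between gene copies and any filter on cells are not given in the sources used here. Each library came with 2 tables of counts, with and without gene names, which held equal values in 19 of 19 libraries, so only the named one was used. The names are those of matching *Strongylocentrotus purpuratus* genes, per the file headers. Of 27232 gene models, 21651 had a name (12761 distinct names, so many names are shared by several models), 5581 had none, and the unnamed models held 20.4% of all UMIs and stayed in library sizes and tests. Among the named models, 3620 were called hypothetical or unknown and were never named in the text. No genome was used here, so no position in the genome is given for any gene model. A RefSeq table of the species was not used, because the names come with the counts.

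The authors also deposited 1 table of marker genes of their own cell clusters. Its columns are a natural log (ln) fold change of a cluster against the other cells (the base is that of the Seurat default and is not stated in the table), and an unadjusted and an adjusted p-value for which cells were the units, per the file headers; its columns of shares of cells were not used here. These p-values of the authors were not used as evidence here, since cells of a library are not replicates; the table served only for an overlap of gene names with the gates described next. It gives no cluster for single cells, so the cell classes used here were built anew and can differ from those of the authors.

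The libraries held between 538 and 5584 cells and between 902539 and 16222078 UMIs. All deposited cells were used, and the smallest had 500 UMIs. Doublets were not called. Instead, cells in the top 1% of UMI totals of their library were left out as an alternative for the gates and the class shares. A list of mitochondrial genome genes matched no name and was therefore not used; the heat shock and stress list served as the other sign of RNA quality. All choices of groups, tests, gene lists, markers and rules for naming genes were made before the data were examined, apart from those said to be chosen afterwards.

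Libraries were placed in 4 stage classes by the stage in the labels: cleavage (2 to 6 hours, n = 5), blastula (7 to 12 hours, n = 6), gastrula (13, 14, 15, 16 and 18 hours, n = 5), and prism and larva (20, 24 and 24 hours, n = 3). Replicate numbers follow the order of the hours within a class. UMIs were summed over the cells of each library and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F test), with 18642 gene models tested in 1 fit over all 19 libraries and Benjamini-Hochberg adjustment at 0.05. A library is 1 time point, so p-values measure the spread between libraries of a class, which holds development within the class as well as technical variation; nothing in the labels says that the libraries came from separate cultures. Standard errors were taken from the log2 fold change and its F value.

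Gene lists were tested with fry (limma 3.58.1) for a shift of their members in 1 direction, adjusted over the 24 lists of a contrast, with camera and an estimated correlation between genes as the alternative. These were the 10 lists of cell type markers (skeletogenic, pigment, blastocoelar, gut, germline and small micromere, apical, neural, ventral ectoderm, dorsal ectoderm and ciliary band) and 14 lists by function (cell cycle, DNA replication and histones, egg and cortical granule, hatching and blastula secreted, cilia, ribosomal proteins, skeletal matrix, pigment and flavin enzymes, gut digestion and differentiation, signalling ligands and receptors, neural function, immune and complement, glycolysis and oxidative phosphorylation, heat shock and stress). The lists overlap; most of the skeletal matrix list lies within the skeletogenic list. Members were matched by name. The pattern for C-lectins took in many numbered lectins of unknown site of expression, and the pattern for histones took in names starting with Cs that belong to other genes and missed the histone names of this annotation, so both lists were also counted without those names, an alternative chosen after seeing the data.

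Cells were also gated by 1 seed gene at a time: Alx1 for skeletogenic cells, Pks1 for pigment cells, Endo16 for gut, FoxQ2 for the apical region, Tbx2/3 for dorsal ectoderm and Nanos2 for the small micromere lineage. Cells with at least 2 UMIs of the seed were summed per library and tested against the sum of the other cells of that library with edgeR and the library as a block, over libraries with at least 20 gated and 20 other cells; both sums of a library come from the same dissociation, which is the source of the pairing. At least 4 such libraries were required. The Alx1 and Nanos2 gates did not meet this at 2 UMIs, and a minimum of 1 UMI, listed as the alternative for this case, gave the values reported. Seed gene models were left out of their own test. Slopes on hours post fertilisation were fitted with edgeR in the gated sums of Alx1 and Pks1.

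For cell classes, all 50943 cells were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, resolution 1). A marker counted for a cluster when it was seen in at least 10% of its cells and was at least 2-fold higher there than in the other cells, with 10 CPM (counts scaled to the size of the library) added to both. A cluster was named "like" a class when at least 3 of its markers counted and its leading 10 genes did not speak for another class. Shares of cells carry exact Clopper-Pearson 95% intervals. Shares of cells passing a gate were taken after thinning each cell to 1204 UMIs, the 10th percentile of all cells, and shallower cells were left out. Levels of single genes are in CPM with exact Poisson 95% intervals; where a library had 0 UMIs of a gene, a floor of 3 UMIs was used. All intervals and floors cover counting error only. The 2 libraries at 24 hours were compared on log2(CPM + 1), over genes above 50 CPM in either, by the number that differed by more than 2-fold, with no test.

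Genes named in the text were taken by rule. For stage contrasts these were the 10 largest rises and 10 largest falls among genes that passed, reached 20 CPM in the higher class and did not overlap between the libraries of the 2 classes. For gates these were the 12 largest folds among genes that passed, reached 20 CPM and were higher in every library tested, and for slopes the 8 steepest each way above 20 CPM. Members of the lists, the leading 10 genes of a cluster, the 5 largest differences each way at 24 hours and the seeds could be named as well. Gene models that share a name may share reads, and their separate values are uncertain to that extent.

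The stage test, the gate test and the slope test were tested on simulated data drawn from the real means and library sizes, with 200 genes changed before filtering. In the stage fits a 4-fold change was recovered for 98% of such genes from cleavage to blastula, 89% from blastula to gastrula and 85% from gastrula to prism and larva, and a 2-fold change for 28%, 31% and 12%, over 18280, 18190 and 18203 genes. False calls made up 3.82%, 4.0% and 4.90% of the calls. Such shares, here and below, describe the simulated data and are not measured error rates of the real libraries, whose hours are ordered. In the gate fits a 2-fold change was recovered for 85% (Alx1, 11093 genes), 96% (Pks1, 10966 genes), 99% (Endo16, 11941 genes, and FoxQ2, 12176 genes), 100% (Tbx2/3, 14723 genes) and 94% (Nanos2, 14079 genes). False calls were 9.76% for Alx1 and 20.5% for Nanos2, and between 4.88% and 6.98% for the other gates. A slope of 0.2 log2 units per hour was recovered for 54.3% of such genes in the Alx1 gate (4598 genes) and 93% in the Pks1 gate (8051 genes). A simulated list of 100 raised genes gave a fry p of 1.98e-17, and 1 of 100 unchanged genes gave 0.813.

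Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, libraries thinned to the shallowest (902539 UMIs), cells under 1000 UMIs left out (3197 cells), a spline of hours in place of classes, 12 and 13 hours left out together, each library left out in turn, gates at other UMI minimums, other cells matched by UMI total, no replicate block, other clustering settings and other minimums at 24 hours. After seeing the data, fits within even or odd hours, with even or odd hour as a covariate, without 15 and 18 hpf (in all libraries, or 1 of them within even or odd hours), without the cells of 1 cluster (cluster 14 or 17) and with only cells of 2000 to 3000 UMIs were added, and slopes on hours were also fitted to the gated cells of cluster 10 (Alx1) or 12 (Pks1) alone, in libraries with at least 20 of these. Figures were drawn with matplotlib 3.10.9; other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0.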

Results

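The series followed transcripts of single cells through the first day of development of the sea urchin *Lytechinus variegatus*, from cleavage to the early larva. The 19 libraries held 50943 cells and 146378605 UMIs. Cleavage had 5 libraries with 8534 cells, blastula 6 with 24176 cells, gastrula 5 with 13450 cells, and prism and larva 3 with 4783 cells. Depth was uneven. The library at 2 hours post fertilisation (hpf) held 538 cells and 902539 UMIs, the one at 6 hpf 5584 cells and 16222078 UMIs, and the libraries from 7 to 12 hpf between 9752742 and 14827414 UMIs. The median UMI count per cell ran from 1213 in 1 library at 24 hpf to 5054 at 3 hpf, with medians of 1334 at 2 hpf and 1416 in the other library at 24 hpf.

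Seed genes of the main embryonic lineages came on one after another. FoxQ2, a transcription factor of the apical ectoderm, went from 13.3 CPM (counts scaled to the size of the library) at 4 hpf to 354 at 5 hpf and 413 at 7 hpf, and was at 41.6 in 1 library at 24 hpf. Tbx2/3, a transcription factor of the dorsal ectoderm, went from 15.8 CPM at 5 hpf to 836 at 10 hpf. Pks1, the polyketide synthase of pigment cells, was at 3.25 CPM at 7 hpf, 55.3 at 8 hpf and 646 at 13 hpf. Endo16, a secreted protein of the gut, went from 9.37 CPM at 9 hpf to 316 at 12 hpf and 1654 at 18 hpf. Alx1, which is required for the skeletogenic lineage, stayed low throughout, with 11.2 CPM at 5 hpf and 15.0 at 6 hpf, and Nanos2, a marker of the small micromeres, reached 9.94 CPM at 7 hpf. Counts of a single library carry counting error only, and no test was run on them.

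**Figure D1:**
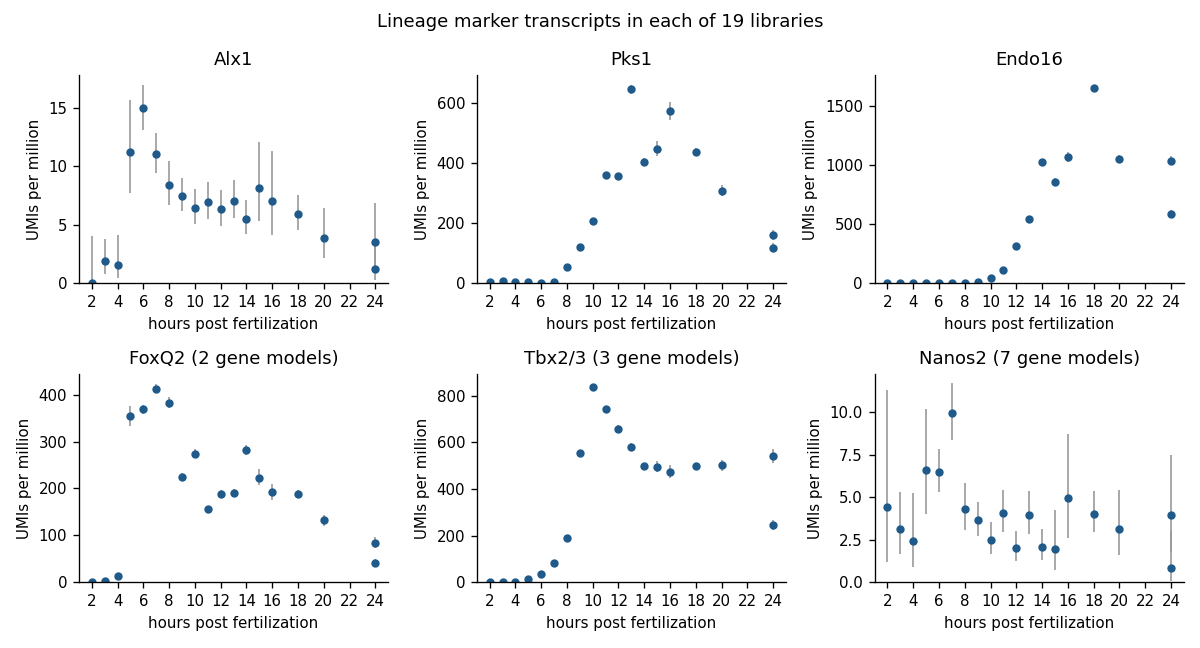
Level of each seed gene in CPM by hours post fertilisation, 1 point per library, on linear axes that start at 0, with exact Poisson 95% intervals that cover counting error only. FoxQ2 is at 354 CPM at 5 hpf, Pks1 at 55.3 at 8 hpf and Endo16 at 316 at 12 hpf, while Alx1 and Nanos2 stay at or below 15.0.

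Of 18642 gene models tested over the 4 stage classes, 13227 (70.95%) changed with stage in edgeR's quasi-likelihood test (adjusted p below 0.05). The class with the highest mean was cleavage for 5043 of them (38.1%), prism and larva for 3672 (27.8%), blastula for 2467 (18.7%) and gastrula for 2045 (15.5%). A spline of hours in place of the classes passed 15637 genes, 13129 of them shared. The share of UMIs in ribosomal protein genes was 0.525% at 2 hpf, 0.729% at 7 hpf, 6.08% at 12 hpf, 12.8% at 18 hpf, and 21.5% and 15.5% in the 2 libraries at 24 hpf. The heat shock and stress list, a sign of RNA quality and dissociation, held 0.997% of UMIs at 2 hpf, 0.413% at 7 hpf, 0.890% at 13 hpf and 0.397% and 0.689% at 24 hpf.

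Libraries of even and odd hours also differed, a pattern that was noticed in the data and that no label names. Over the 8 libraries from 7 to 14 hpf, with a quadratic curve of hours in the model, 3677 of 17202 gene models (21.4%) differed between even and odd hours (edgeR adjusted p below 0.05), 1990 higher in even and 1687 higher in odd hours, with a median size of 0.51 on the log2 scale. Hunk (L_var_08258) was higher in even hours by 2.07 ± 0.15 (SE) on the log2 scale, at 24.6 against 5.57 CPM (n = 4 and 4). A model named EhH3_57 (L_var_17419) was at 19.9 CPM in even and 108 in odd hours. Among the largest differences each way, the models with histone names, EhH3_57, EhH4_79, EhH2b_94, Lhh2ac and Lhh2af, were higher in odd hours. Histones were not tested as a group, since the pattern of their list missed such names. The genes named here were chosen after their values were seen, among the largest differences. The alternation appeared weaker or absent outside these hours. Its genes and its size were taken from the fit to 7 to 14 hpf, however, which raises the slopes within those hours. Over the genes that passed, the step from each odd to the next even hour from 7 to 14 hpf had a slope of 0.815 to 0.892 on the even minus odd difference, and steps from 2 to 7 hpf alternated in sign (0.296 and 0.606 upward). The slope was -0.227 from 14 to 15 hpf and 0.0697 from 15 to 16 hpf. Between even hours it was -0.593 from 16 to 18 hpf and 0.227 from 18 to 20 hpf. Over these genes as a set, the library at 15 hpf lay nearer the even hours before it and the one at 18 hpf nearer the odd ones. Single genes differed in this. Myt1_1 was at 160 CPM at 13 hpf, 41.7 at 14 hpf, 30.6 at 15 hpf and 91.8 at 18 hpf, but Hunk was at 19.2 CPM at 14 hpf and 5.88 at 15 hpf, near its odd hours. Stage contrasts are also given within even and within odd hours, which separate the 2 kinds of library up to 14 hpf and mix them in the gastrula, and without 15 and 18 hpf.

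**Figure D2:**
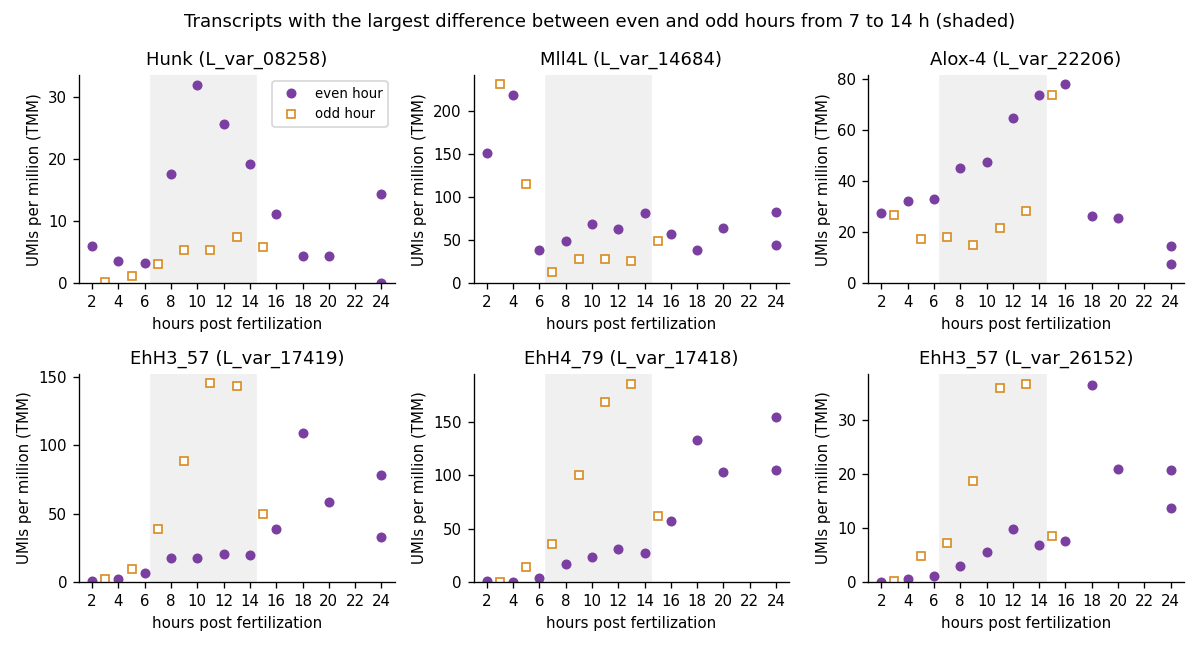
TMM-scaled CPM by hours post fertilisation for 6 gene models with large differences between even hours (filled circles) and odd hours (open squares), 1 point per library; the hours from 7 to 14, over which the difference was fitted, are shaded. Over those hours Hunk averages 24.6 CPM in even and 5.57 in odd hours, and EhH3_57 (L_var_17419) 19.9 and 108.

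From cleavage to blastula, members of the skeletogenic, gut and other cell type lists rose, and more cell cycle genes fell than rose. Of the skeletogenic genes, P19 rose from 0.778 to 831 CPM (log2 fold change 9.14 ± 0.96 SE, n = 5 and 6). A model of P16 (L_var_11249), a transmembrane protein of skeleton formation, had 1 UMI in all cleavage libraries and a pooled ratio of 7029 (95% counting interval 1261 to 277647). Other large rises were those of Cryz_1 (8.25 ± 1.47), FReD (8.00 ± 1.05), Sarmr2 (7.92 ± 0.92), Mtmmpe (7.57 ± 0.94), and Mif5, with 3 UMIs in cleavage and a ratio of 916 (interval 313 to 4443). The largest falls were those of 2 models of Cdc20, the activator of the anaphase-promoting complex (-7.48 ± 0.72 and -6.45 ± 0.56), Homeo1 (696 to 3.88 CPM, -7.47 ± 0.71), TrafA (-6.59 ± 0.69), Galr2L_16 (-6.45 ± 0.66) and Cpeb1, a regulator of maternal mRNA polyadenylation (367 to 9.14 CPM, -5.32 ± 0.51).

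By list, 39 of 72 tested skeletogenic members rose from cleavage to blastula and 0 fell (39 and 0 adjusted over the list alone), and without numbered C-lectins 25 of 36 rose. Of the ribosomal protein genes, 74 of 82 rose (75 adjusted over the list alone), for example Rps19 (4.92 ± 0.81) and Rpl13a (4.59 ± 0.64). Of 25 gut members, 13 rose and 2 fell (the same counts adjusted over the list alone), with Endo16 at 5.58 ± 1.19, FoxA at 5.20 ± 0.62 and Bra at 4.91 ± 0.69. Of 16 blastocoelar members, 12 rose and 2 fell (12 and 2 adjusted over the list alone), including Scl (6.12 ± 0.89) and, downward, Ets4 (-2.73 ± 0.25). Of 12 ventral members 9 rose (9 adjusted over the list alone), such as FoxG (4.90 ± 0.96) and Chordin (2.64 ± 0.70), of 18 apical members 11 (11), such as Rax (4.05 ± 0.54), and of 30 dorsal members 14 rose and 6 fell (14 and 6), with Tbx2/3 at 5.26 ± 0.87 and Arsb at -2.91 ± 0.37. Of 20 pigment members 11 rose and 2 fell (11 and 2), and of 34 signalling ligands and receptors 18 rose (18), such as Wnt5 (3.71 ± 0.62). In glycolysis and oxidative phosphorylation 34 of 59 rose and 3 fell (34 and 3 adjusted over the list alone). In the cell cycle list, 5 of 25 rose and 11 fell (6 and 11 adjusted over the list alone), with CycA at -3.06 ± 0.40 and, upward, CycD at 1.37 ± 0.30. DNA replication and histones had 14 rises and 22 falls among 61 (14 and 22 adjusted over the list alone); its median was 0.18 on the log2 scale while its test pointed down, and without names starting with Cs there were 4 rises and 11 falls among 23, including Orc1 (-3.94 ± 0.29) and Cdc6 (-3.51 ± 0.43). By fry, 20 of 24 lists passed, and none did in camera, where the adjusted p with an estimated correlation was 0.390 for the skeletogenic, gut and cell cycle lists, 0.517 for ribosomal proteins and at most 0.797 for the others of the 20 (2 lists had an unadjusted p under 0.05). Within odd hours 7 lists passed fry.

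In all, 10569 genes passed from cleavage to blastula in edgeR, 5900 up and 4669 down. Of the genes tested, 6218 (33.4%) did not overlap between the libraries of the classes, against 0.433% for libraries in random order. The hours of the classes are ordered, so a steady drift over time also keeps them apart. TMM scaling left a median log2 change of 0.28 over all genes, against 0.38 with RLE and 0.53 with no scaling (55.8%, 60.4% and 66.4% of calls upward), so the changes are relative to that shift. Within even hours (n = 3 and 3) 6337 genes passed, 3061 up and 3276 down, and within odd hours (n = 2 and 3) 5763, 2791 up and 2972 down.

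From blastula to gastrula, 52 of 82 ribosomal protein genes rose and 10 of 25 cell cycle genes fell. For each list the adjusted p was 0.527 with an estimated correlation. Without 15 and 18 hpf (n = 6 and 3), 1 of 81 ribosomal protein genes rose and 2 of 25 cell cycle genes fell, and neither list passed fry (adjusted p = 0.0905 and 0.105). Among the largest single changes, Aqp8, a water channel, rose by 6.25 ± 0.68 on the log2 scale (0.333 to 26.3 CPM, n = 6 and 5), 3 models of Fpgs, a folate polyglutamylating enzyme, by 4.17 to 5.66, the sulfotransferase Sult1b1_1 by 4.00 ± 0.86 and the protease Astacin4 by 3.75 ± 0.58. He1, the hatching enzyme, fell from 74.7 to 1.48 CPM (-5.52 ± 1.52), as did Rxfp2L_4 (-6.68 ± 1.32), the matrix metalloprotease Mmp1/3L1 (-6.50 ± 1.61), Nop2 (-5.24 ± 1.23), Igf1 (-4.88 ± 0.85) and GmnnL, named for the replication inhibitor geminin (-3.82 ± 0.67). Of the 20 genes named by rule here, 5 lost the call without 15 and 18 hpf, all falls, among them He1 (-5.03 there), Mmp1/3L1 (-6.23) and Nop2 (-4.90). Within even hours 7 lost it, within even hours without 18 hpf 15 and within odd hours 20, and none reversed. They were chosen for not overlapping between the classes, so fewer libraries could hardly reverse them. With even or odd hour as a covariate over all libraries 0 of the 20 lost it. Of the ribosomal protein genes 76 rose adjusted over the list alone, for example Rpl15_1 (2.22 ± 0.34). In the cell cycle list 1 of 25 rose and 10 fell (2 and 12 adjusted over the list alone), with CycA at -1.89 ± 0.40, Wee1 at -2.13 ± 0.41 and Plk1 at -0.99 ± 0.26. In the cilia list 2 of 68 rose and 15 fell (2 and 17 adjusted over the list alone), with Tektin2 at -2.67 ± 0.53 and, upward, Bbs5 at 2.52 ± 0.50. Of 103 neural function members 20 rose and 7 fell (22 and 7 adjusted over the list alone), among them potassium channels such as Kcnc1 (3.79 ± 0.54) and Kcnk16 (3.45 ± 0.54) and acetylcholine receptor subunits such as Chrna9_5 (2.15 ± 0.52). Of 16 egg and cortical granule members 5 fell (6 adjusted over the list alone), such as Btg4 (-1.17 ± 0.29).

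These 5 lists and both pigment lists passed fry from blastula to gastrula (adjusted p of 0.0144 to 0.0267), none of them in camera (adjusted p = 0.527 to 0.570 with an estimated correlation; 0 lists had an unadjusted p under 0.05). The pigment list passed although 0 of its 20 members passed edgeR on their own (9 had an unadjusted p under 0.05, all upward), and 0 of 15 pigment and flavin enzymes did (6 unadjusted, all upward). Within even hours these 7 lists had fry adjusted p of 0.0871 to 0.291 and within odd hours of 0.257 to 0.301, and without 15 and 18 hpf of 0.0905 to 0.138, so none passed there. With even or odd hour as a covariate over all libraries, 7 of 24 lists passed fry, though that fit counts 15 hpf as odd and 18 hpf as even. The cilia call was lost without blastula replicate 1, 2 or 3 or gastrula replicate 3 or 4 (fry adjusted p of 0.0504 to 0.0621), and the neural function call without blastula replicate 2, 3, 4 or 5 or gastrula replicate 4 (0.0545 to 0.0759). Of 20 gut digestion members 4 rose and 2 fell (5 and 3 adjusted over the list alone; fry adjusted p = 0.879), and of 10 hatching and blastula secreted members 1 rose (2 rose and 1 fell adjusted over the list alone; fry adjusted p = 0.437). The skeletogenic list did not pass (fry adjusted p = 0.0684), with 10 rises and 3 falls among 72 (20 and 5 adjusted over the list alone), such as Sm30A, a spicule matrix protein (3.38 ± 0.79). Of the signalling list 7 rose and 1 fell (7 and 2), with Hh at 3.45 ± 0.85 and Univin at -1.32 ± 0.32, and of the dorsal list 6 rose and 1 fell (6 and 1), with Hox7 at 3.24 ± 0.75.

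A total of 3145 genes passed from blastula to gastrula in edgeR, 1521 up and 1624 down, and 2414 (12.9%) did not overlap between the classes. Without 15 and 18 hpf 703 passed, 441 up and 262 down. Within even hours (n = 3 and 3, with 18 hpf among them) 386 passed, 272 up and 114 down, and 43 without 18 hpf. Within odd hours (n = 3 and 2, the 2 being the unlike libraries at 13 and 15 hpf) edgeR passed 0, with 2563 at an unadjusted p under 0.05. Without blastula replicate 2 (8 hpf) 2063 passed, and without gastrula replicate 5 (18 hpf) 1887.

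From gastrula to prism and larva, more genes rose than fell. Fabp2L2, a fatty acid binding protein by name, rose from 47.7 to 3130 CPM (log2 fold change 6.03 ± 0.94, n = 5 and 3), 2 genes named for lactase, Lct_11 and Lct_2, by 6.83 ± 0.79 and 5.87 ± 0.67, the apolipoprotein Apod by 5.85 ± 0.69, and B4galt5_1 by 5.71 ± 0.72. The largest falls were those of EhH3_57 (L_var_03117, -3.51 ± 0.62), 3 models of Yp303 and 1 of YP30/FascL_5 (-2.62 to -2.20), Snrnp35_1 (-1.99 ± 0.29), and Ovo (-1.90 ± 0.46). Of the 20 genes named by rule here, 8 lost the call without prism and larva replicate 2, 8 without replicate 3 and 8 within even hours, all among the falls, with Yp303, YP30/FascL_5 and Ovo each time. Within even hours without 18 hpf 13 lost it, 5 of them rises, among which were Lct_11 (adjusted p = 0.0645), Lct_2 (0.0506) and B4galt5_1 (0.0692). Fabp2L2 led the gut-like cluster 17, of whose 278 cells 230 came from replicate 3, 45 from replicate 2 and 3 from replicate 1. It rose by 5.11 without that cluster and by 5.65 without replicate 3, and Lct_11 and Lct_2 rose by 4.99 and 4.47 without the cluster. Apod and B4galt5_1 also led cluster 14, which held most of the 52.9% unnamed cells of 1 library at 24 hpf (replicate 3), and rose by 4.82 and 4.09 without that cluster and by 4.61 and 3.81 without that library. Of 15 neural members 4 rose (5 adjusted over the list alone), namely Brn3 (4.13 ± 0.53), Otp in 2 models (3.64 ± 0.69 and 3.33 ± 0.66) and Th, the rate-limiting enzyme of dopamine synthesis (1.83 ± 0.50). This was the only list to pass fry (adjusted p = 0.0228), and it did not pass in camera (adjusted p = 0.472 with an estimated correlation, and 1 list had an unadjusted p under 0.05). Its fry adjusted p was 0.384 within even hours, 0.198 without the cells of cluster 14 and 0.426 with cells of 2000 to 3000 UMIs only, and between 0.0527 and 0.0799 without gastrula replicate 1, 3 or 4 or prism and larva replicate 1 or 3. Fry passed 1 of 24 lists with even or odd hour as a covariate, 1 without cluster 17 and 1 without 15 and 18 hpf. Of 20 gut digestion members 1 rose (2 adjusted over the list alone; fry adjusted p = 0.551). Of 25 gut members 5 rose (5 adjusted over the list alone; fry adjusted p = 0.350), among them 2 models of Lox, a hindgut factor (5.04 ± 0.74 and 5.11 ± 0.76), FoxD_1 (4.59 ± 0.79) and Brn1/2/4 (3.28 ± 0.71). Of 103 neural function members 5 rose (10 rose and 1 fell adjusted over the list alone; fry adjusted p = 0.0840). Of 37 heat shock and stress members 3 rose and 1 fell (6 and 1 adjusted over the list alone; fry adjusted p = 0.809), with Hsp701D at 3.49 ± 0.75.

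A total of 625 genes passed from gastrula to prism and larva in edgeR, 521 up and 104 down (83.4% up, and 72.8% with no scaling). Of the genes tested, 3001 (16.1%) did not overlap between the classes, where a random order of libraries gives 3.57% and a steady drift over the hours gives more. Within even hours (n = 3 and 3) 65 passed, 62 up and 3 down, and 55 without 18 hpf; prism and larva had no library at an odd hour. The count rested on single libraries: without gastrula replicate 1, 2 or 3 (13, 14 and 15 hpf) it was 317, 328 and 413, without prism and larva replicate 2 or 3 (both 24 hpf) 314 and 159, and without replicate 1 (20 hpf) 937.

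**Figure D3:**
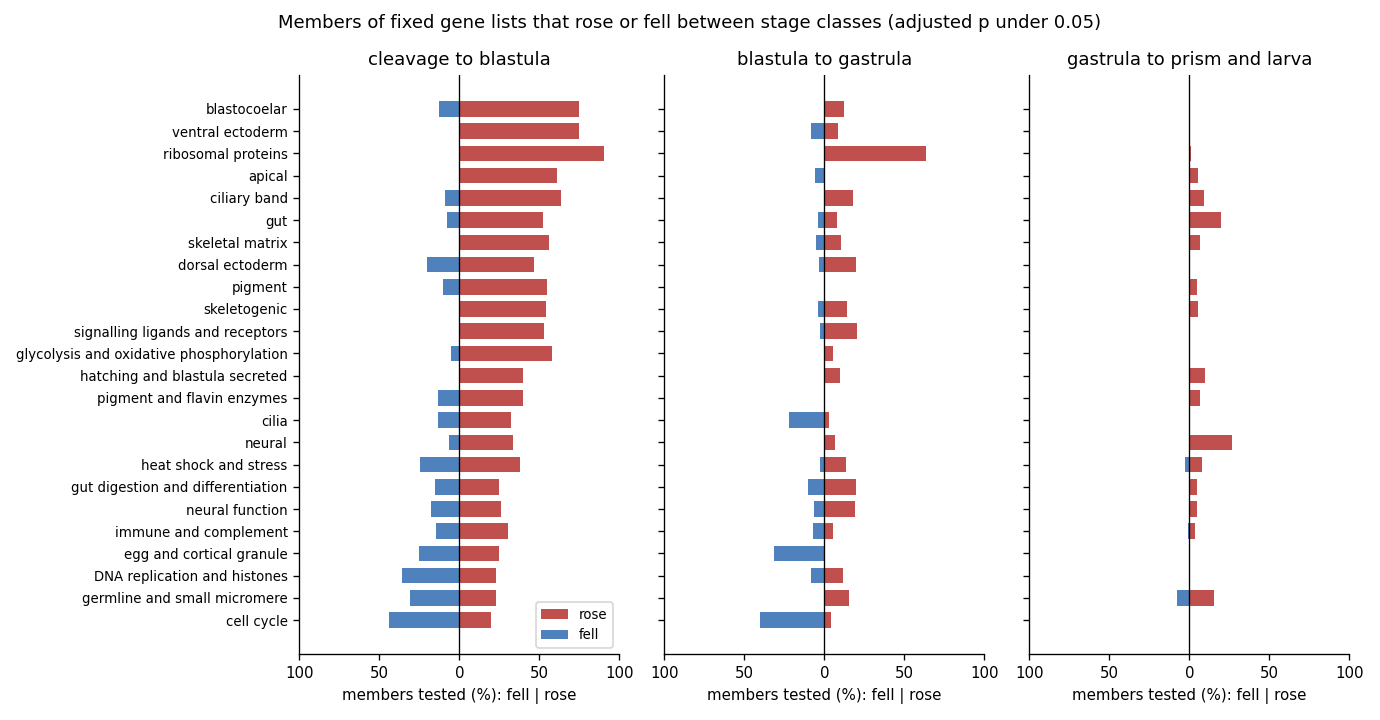
Percent of the tested members of each list that rose or fell (edgeR adjusted p below 0.05) in the 3 successive stage contrasts. From cleavage to blastula 74 of 82 ribosomal protein genes rose, while 11 of 25 cell cycle genes fell.

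Clustering all cells together gave 17 clusters, of which 11 were named by markers. Skeletogenic-like cells (cluster 10) were led by P16 and P19, pigment-like cells (12) by Cryz_1 and Pks1, apical-like cells (13) by RapL, Nkx3-2, FoxQ2_1 and Zic, dorsal-like cells (3) by Hox7, IrxA and Unc4.1_1, and ventral-like cells (1) by genes that included Chordin and FoxG. Gut-like cells fell into clusters 5, 7, 9 and 17, led by Endo16, Hnf1_1 and FoxA in cluster 5 and by Bra, Wnt5 and Hox11/13b in cluster 7; cluster 17 had 82.7% of its 278 cells from 1 library at 24 hpf (replicate 3). Blastocoelar-like cells made up clusters 11 and 15, each with 9 blastocoelar markers, which also held 8 and 5 pigment markers, so the name of cluster 11 rests on a small margin. No cluster was named for the germline, neural or ciliary band lists. Shares describe these dissociations. Gut-like cells were 1.22% of cells at 6 hpf, 33.2% at 7 hpf, 22.6% at 12 hpf and 21.5% at 18 hpf. They were mostly of cluster 9 at 7 hpf, cluster 7 at 9 hpf and cluster 5 in the gastrula. Cluster 9 had Hox11/13b, Nop2 and Wnt1 but not Endo16 among its leading genes, and Endo16 was at most 2.64 CPM before 9 hpf. The early share thus rests on other markers of the list, and the shares at 7 and 18 hpf are of different clusters. Dorsal-like cells went from 3.71% at 10 hpf to 18.5% at 12 hpf, and ventral-like cells from 1.80% to 26.7% over the same hours, while cells of unnamed clusters went from 45.1% to 9.24%. Of these, cluster 2, most of the unnamed cells at 10 hpf, held 4 ventral and 2 dorsal markers. Pigment-like cells were 0.19% at 10 hpf and 7.11% at 12 hpf, although Pks1 was already at 55.3 CPM at 8 hpf. At 8 and 10 hpf most cells that passed the Pks1 gate lay in the blastocoelar-like cluster 11. Over the 5 gastrula libraries, ventral-like cells made up 31.7% ± 2.8 (SD), dorsal-like 22.3% ± 1.7, gut-like 20.8% ± 1.3, pigment-like 8.35% ± 0.77, blastocoelar-like 5.42% ± 0.92, apical-like 4.66% ± 0.32 and skeletogenic-like 4.30% ± 0.45. These shares depended on the clustering. Without the top 1% of cells by UMIs, ventral-like cells were 0% and apical-like cells 14.7%, at resolution 0.5 no cluster was named for pigment or blastocoelar cells (0% each), and 4000 variable genes gave 2.89% apical-like cells. At 24 hpf ventral-like cells were 10.1% and 0.36% in the 2 libraries, and unnamed cells, mostly of cluster 14, 24.9% and 52.9%. That cluster of 1602 cells was led by B4galt5_1 and Apod and had a median of 1160.5 UMIs.

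**Figure D4:**
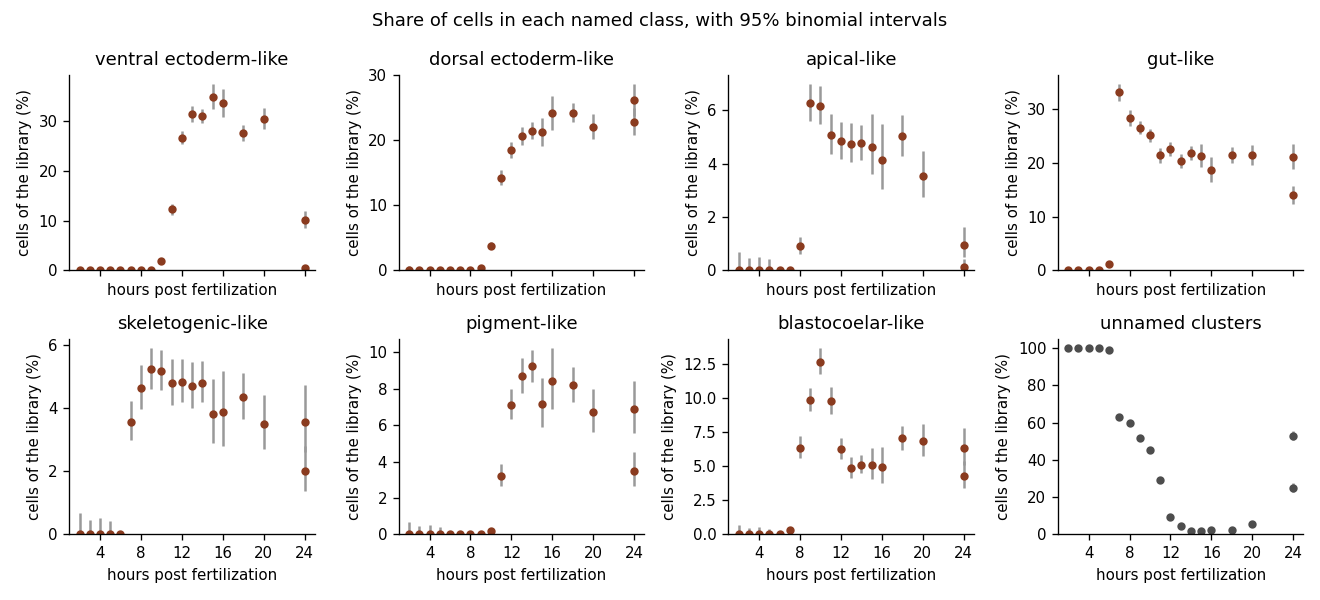
Percent of cells in each class by hours post fertilisation, 1 point per library, with exact 95% binomial intervals for counting error; the last panel holds cells of unnamed clusters. Gut-like cells are 33.2% of cells at 7 hpf (mostly cluster 9) and 21.5% at 18 hpf (mostly cluster 5), and unnamed cells 24.9% and 52.9% in the 2 libraries at 24 hpf.

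Many genes of the larval skeleton were higher in cells with Alx1. Over 11 libraries (5 to 18 hpf, 811 gated cells at 1 or more UMI), P16 was higher than in the other cells of the same library, by 4.86 ± 0.26 on the log2 scale for L_var_11117 (in 9 of 11 libraries and lower in 2) and by 4.43 ± 0.16 for L_var_11249 (in 9 and lower in 1). Also higher were the spicule matrix gene Sm37 by 4.82 ± 0.21 and Pm27 by 4.79 ± 0.29 (each in 7 of 11 and lower in 2). The C-lectin Clect was higher by 4.59 ± 0.23 (24.0-fold, 11 of 11), Msp130, a surface glycoprotein of these cells, by 4.56 ± 0.18 (10 of 11), and Vegfr10, a receptor for growth factor signals that guide them, by 4.19 ± 0.18 (10 of 11). Rabrp3 (4.49 ± 0.19), B4galt6_8 (4.31 ± 0.14), Trpm3L (4.27 ± 0.28) and ElavL (3.33 ± 0.19) were higher in 11 of 11. The regulators Tbr (2.85 ± 0.25, 10 of 11), Erg (2.86 ± 0.16) and Ets1/2 (2.55 ± 0.21) were also higher. Of 28 skeletogenic members 21 were higher and 3 lower (22 and 4 adjusted over the list alone; adjusted p = 0.0673 with an estimated correlation), and without numbered C-lectins 20 of 22 were higher. Of 12 blastocoelar members 9 were higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0673 with an estimated correlation). Of 12 apical members 0 were higher and 11 lower (the same adjusted over the list alone; adjusted p = 0.0678 with an estimated correlation). In all 3290 genes passed, 1407 higher and 1883 lower. Gated cells were 1.19 ± 0.13 (SD) times as deep as the others. In the gastrula Alx1 was seen in 12.3% of skeletogenic-like cells thinned to 1204 UMIs and in 0.0371% of gut-like cells (median depths 2801 and 2828). Without thinning, as the gate was applied, the shares were 26.8% and 0.297%, so most skeletogenic-like cells lay among the other cells.

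Cells with Pks1 differed from the others by large folds. Over 13 libraries (8 to 24 hpf, 2589 gated cells), Cryz_1, a quinone oxidoreductase by name, was 212-fold higher (13830 against 51.1 CPM, log2 7.73 ± 0.42), Acly_2, a citrate lyase, 132-fold (7.05 ± 0.33), and Slc10a2L_3, Slc45, Sdr, Slc15a4, 2 models of Odc1, Mif4 and Mif5 by 6.18 to 6.81 on the log2 scale, each in 13 of 13 libraries. The pigment genes Fmo5_1 (6.10 ± 0.33), Fmo2_2 (5.79 ± 0.25), Sult1c_2 (5.60 ± 0.28), Gcm, the regulator of pigment cell fate (5.26 ± 0.26), and Mitf (2.45 ± 0.31) were higher. Of 15 pigment members 8 were higher and 3 lower (8 and 3 adjusted over the list alone; adjusted p = 0.0610 with an estimated correlation), and of 39 immune and complement members 14 were higher and 7 lower (15 and 7; adjusted p = 0.0963 with an estimated correlation). Of 11 ventral members 11 were lower, of 15 gut members 12, and of 57 cilia members 2 were higher and 35 lower (11, 12, and 2 and 38 adjusted over the list alone; adjusted p = 0.0755, 0.251 and 0.104 with an estimated correlation). In all 5141 genes passed, 2394 higher and 2747 lower, with gated cells 1.22 ± 0.09 times as deep.

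Cells with Endo16 carried the regulators of the endoderm. Over 12 libraries (9 to 24 hpf, 5014 gated cells), Sult1b1_1 was 19.2-fold higher (4.26 ± 0.24), 2 models of Apobec1 by 3.83 ± 0.29 and 3.42 ± 0.26, and the endodermal factors FoxA by 3.26 ± 0.18, Tgif by 3.04 ± 0.24 (11 of 12), Blimp1 by 2.90 ± 0.22, Hnf1_1 by 2.78 ± 0.22 and Gatae by 2.45 ± 0.22 (11 of 12). Of 15 gut members 11 were higher and 2 lower (the same adjusted over the list alone), and the list also passed in camera (adjusted p = 0.00623 with an estimated correlation). Of 79 ribosomal protein genes 78 were higher (78 adjusted over the list alone; adjusted p = 0.249 with an estimated correlation), and of 5 germline members 4, including the RNA helicase Vasa (1.38 ± 0.12; 4 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation). Of 58 cilia members 2 were higher and 48 lower (3 and 48 adjusted over the list alone; adjusted p = 0.146 with an estimated correlation). Lower were also 18 of 21 skeletal matrix members, 11 of 11 ventral and 13 of 16 pigment members (18, 11 and 13 adjusted over the list alone, with 1 pigment member higher; adjusted p of 0.0267 for each with an estimated correlation). In all 6150 genes passed, 2943 higher and 3207 lower, with 376 and 1358 of them beyond 2-fold and gated cells 1.28 ± 0.18 times as deep.

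Cells with FoxQ2 were enriched for regulators of the apical ectoderm and for cilia genes. Over 16 libraries (5 to 24 hpf, 4928 gated cells), Dkk3, a secreted protein of the Dickkopf family, was 70.4-fold higher (6.14 ± 0.30), RapL higher by 5.27 ± 0.31 and the secreted Wnt antagonist Sfrp1/5 by 4.07 ± 0.29. Of the homeobox genes, Nkx3-2 was higher by 6.53 ± 0.35 (15 of 16), Nkx2-1 by 4.34 ± 0.30, Hbn by 4.08 ± 0.21 (15 of 16) and Rax by 3.40 ± 0.23 (14 of 16). Of 14 apical members 11 were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.0057 with an estimated correlation). Of 59 cilia members 37 were higher and 3 lower (41 and 4 adjusted over the list alone; adjusted p = 0.0468 with an estimated correlation), including Tektin3 (1.91 ± 0.23) and FoxJ1, the regulator of motile cilia (1.31 ± 0.14). Of 16 gut members 16 were lower, of 21 dorsal members 1 was higher and 11 lower, and of 28 skeletogenic members 20 were lower (16 gut, 12 dorsal and 20 skeletogenic members lower, and 2 dorsal and 2 skeletogenic members higher, adjusted over the list alone; adjusted p = 0.00167, 0.0057 and 0.0293 with an estimated correlation). In all 2910 genes passed, 1302 higher and 1608 lower, with gated cells 1.14 ± 0.09 times as deep.

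In cells with Tbx2/3 most changes were small. Over 15 libraries (6 to 24 hpf, 12836 gated cells), the dorsal homeobox genes Dlx (1.79 ± 0.12, in 14 of 15 libraries), Unc4.1_1 (1.74 ± 0.17, 14 of 15), Msx (1.73 ± 0.12, 14 of 15), Hox7 (1.67 ± 0.13, 12 of 15) and IrxA (1.48 ± 0.12, 13 of 15) were higher, as were HesD (1.16 ± 0.08) and Wnt5 (0.99 ± 0.07) in 15 of 15. Of 21 dorsal members 13 were higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 0.00549 with an estimated correlation). Of 80 ribosomal protein genes 66 were lower (73 adjusted over the list alone; adjusted p = 0.0536 with an estimated correlation), and so were 16 of 18 apical and 12 of 14 blastocoelar members (17 and 12 adjusted over the list alone; adjusted p = 0.00295 for each with an estimated correlation). In all 2972 genes passed, 1173 higher and 1799 lower, but only 27 and 206 beyond 2-fold. With no replicate block 57 passed. Gated cells were 1.20 ± 0.08 times as deep.

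Cells with Nanos2 gave few calls. Over 10 libraries (6 to 18 hpf, 505 gated cells at 1 or more UMI) 416 genes passed, 60 higher and 356 lower, and RLE scaling gave 158 with 100 higher and 58 lower, so the balance of directions depended on the scaling. With other cells matched by UMI total 38 passed and with DESeq2 38, and with no replicate block edgeR passed 0 (819 at an unadjusted p under 0.05). Gated cells were 1.21 ± 0.14 (SD) times as deep as the others. Alx1 (1.40 ± 0.32, in 4 of 10 libraries), Msp130r1 (1.17 ± 0.27, 4 of 10) and Delta (0.81 ± 0.17, 7 of 10) were higher. Delta passed with matched cells (adjusted p = 0.0475) and not in DESeq2 (0.0806), Alx1 and Msp130r1 were not tested with matched cells and had no adjusted p in DESeq2, and none of these passed with no replicate block (0.850 to 0.884). Of 8 germline members 0 passed edgeR (0 had an unadjusted p under 0.05), and of 10 ciliary band members 2 were lower (4 adjusted over the list alone; adjusted p = 0.0254 with an estimated correlation). Without blastula replicate 3 (9 hpf) 263 genes passed, and without replicate 6 (12 hpf) 636. False calls were 20.5% in the simulation of this gate. Nanos2 was seen in 0.594% of gut-like cells of the gastrula thinned to 1204 UMIs and in 0 of 553 skeletogenic-like cells, which allows up to 0.665% of cells with a UMI at that depth. Without thinning the shares were 1.48% and 0.542%.

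**Figure D5:**
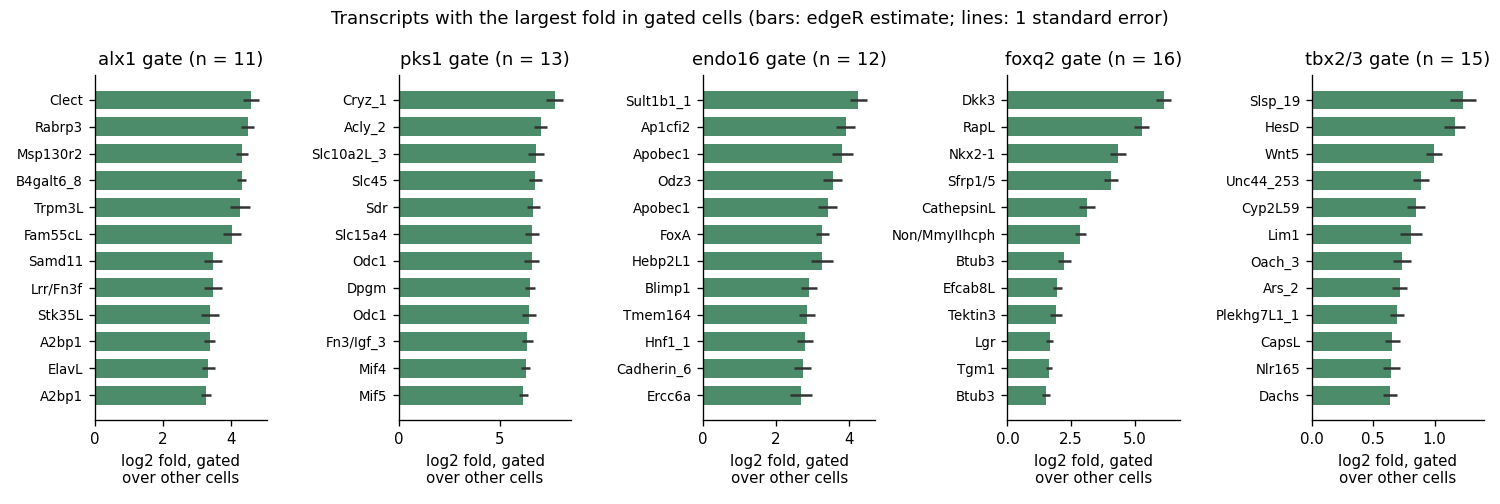
Log2 fold change (bars; lines, 1 SE) of the 12 named genes with the largest fold in each of 5 gates, gated against other cells of the same library. Bars reach 7.73 for Cryz_1 in Pks1 cells and 1.23 for Slsp_19 in Tbx2/3 cells.

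Within even hours the gates passed 2034 genes for Alx1, 3642 for Pks1, 5372 for Endo16, 2083 for FoxQ2, 1749 for Tbx2/3 and 105 for Nanos2, and within odd hours 1416, 3267, 3415, 1130, 895 and 400. Pks1, Endo16 and FoxQ2_1 were among the 10 leading genes of clusters 12, 5 and 13, so their shares in the classes named for these clusters were partly built in, and those in the other classes give the background. Among gastrula cells thinned to 1204 UMIs, 2 or more UMIs of Pks1 were seen in 90.0% of pigment-like and 0.362% of skeletogenic-like cells (median depths 2919 and 2801), of FoxQ2 in 75.5% of apical-like and 0.904% of skeletogenic-like cells (2549.5 and 2801), of Endo16 in 72.9% of gut-like and 3.07% of skeletogenic-like cells (2828 and 2801), and of Tbx2/3 in 28.1% of dorsal-like and 7.64% of blastocoelar-like cells (2391.5 and 2945). Without thinning, as the gates were applied, the shares were 98.1% and 0.723% for Pks1, 91.4% and 2.17% for FoxQ2, 85.8% and 6.33% for Endo16, and 50.7% and 19.4% for Tbx2/3. The mean share of gastrula cells passing was 18.4% ± 4.1 (SD, n = 5) for Endo16, 16.2% ± 1.5 for Tbx2/3, 7.78% ± 0.98 for Pks1 and 5.36% ± 0.73 for FoxQ2, and 22.2%, 30.4%, 8.62% and 7.38% without thinning. In the gastrula and the prism and larva libraries, without thinning, cells passing both Pks1 and Tbx2/3 numbered 620, against 433 were the gates independent, and made up 43.5% of the 1425 cells there that passed Pks1. Pks1 was likewise higher in Tbx2/3 cells by 0.59 ± 0.14 (SE), and Tbx2/3 in Pks1 cells by 0.44 ± 0.17. The other pairs fell below independence, for example 113 cells with Pks1 and Endo16 against 317.

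Skeleton genes were higher in Alx1 cells of later hours. In Alx1 cells (11 libraries, 5 to 18 hpf), 2463 of 5187 genes had a slope on hours in edgeR, 1211 rising and 1252 falling. Sm29 rose by 1.26 ± 0.21 log2 units per hour, P16 (L_var_11249) by 1.19 ± 0.23, Alx4 by 1.07 ± 0.21, Sm37 by 0.99 ± 0.20 and Sm30A by 0.98 ± 0.14. Endo16 rose by 0.99 ± 0.10, where its background of 3.07% in skeletogenic-like cells (6.33% without thinning) and its rise in whole libraries apply. He1 (-1.35 ± 0.16), 2 models of Wnt1 (-1.03 ± 0.18 and -0.97 ± 0.17) and Igf1 (-0.94 ± 0.09) fell. Of 17 skeletal matrix members 15 rose (16 adjusted over the list alone), of 71 ribosomal protein genes 71 (71 adjusted over the list alone), and of 12 cell cycle members 10 fell (10 adjusted over the list alone). Early and late Alx1 cells lay in different clusters. At 6 hpf 76.3% of them were in the unnamed cluster 16, which had Alx1 and Wnt1 among its leading genes, and 0.578% in the skeletogenic-like cluster 10, which held 56.1% at 7 hpf and 91.4% at 13 hpf. In the Alx1 cells of cluster 10 alone (9 libraries, 7 to 18 hpf), 1867 of 4227 genes had a slope, with Sm29 at 1.12 ± 0.25, P16 (L_var_11249) at 0.83 ± 0.18, Sm30A at 0.81 ± 0.13 and Endo16 at 0.57 ± 0.11. There both models of Wnt1 fell (-1.75 ± 0.08 and -1.48 ± 0.10), 15 of 18 skeletal matrix members rose (16 adjusted over the list alone), and He1 and Igf1 were too low to be tested. In Pks1 cells (13 libraries, 8 to 24 hpf), 2753 of 8499 genes had a slope, 1269 rising and 1484 falling. Fabp2L2 rose by 0.85 ± 0.06 per hour; it also led the gut-like cluster 17 (19998.5 against 93.3 CPM in the other cells) and rose in whole libraries, and RNA from other cells was not removed from its count. The potassium channel Kcnk16 rose by 0.53 ± 0.07 per hour and Maoa_2, a monoamine oxidase, by 0.46 ± 0.05, while Hs3st2 (-0.98 ± 0.07), Wscd1 (-0.87 ± 0.10), Nop2 (-0.76 ± 0.04) and Epdmnrp2 (-0.64 ± 0.06) fell. Of 77 ribosomal protein genes 68 rose (72 adjusted over the list alone), of 12 pigment members 1 (1 adjusted over the list alone), and of 11 blastocoelar members 9 fell (9 adjusted over the list alone). Here too the clusters changed with time. Of the Pks1 cells, 93.2% at 8 hpf and 95.9% at 10 hpf lay in the blastocoelar-like cluster 11, which Hs3st2 and Epdmnrp2 led, and 78.4% at 12 hpf and 91.3% at 13 hpf in the pigment-like cluster 12. In the Pks1 cells of cluster 12 alone (10 libraries, 11 to 24 hpf), 1501 of 5409 genes had a slope. Hs3st2 (-1.12 ± 0.07), Nop2 (-0.68 ± 0.06) and Epdmnrp2 (-0.77 ± 0.07) fell there as well, Fabp2L2 (0.89 ± 0.06), Kcnk16 (0.44 ± 0.07) and Maoa_2 (0.57 ± 0.05) rose, and Wscd1 was too low to be tested. Of 76 ribosomal protein genes 45 rose and 1 fell (56 and 1 adjusted over the list alone), of 9 pigment members 5 fell (5), and of 7 blastocoelar members 1 rose and 6 fell (1 and 6). Within even hours 1115 and 1530 genes had a slope in Alx1 and Pks1 cells, and within odd hours 1098 and 1457. With even or odd hour as a covariate over all libraries of each gate, 2665 and 2640 genes had one.

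The only repeated time point was 24 hpf. Its 2 libraries had a Pearson correlation of 0.947 and a Spearman correlation of 0.933 across genes, which are not independent replicates, and 564 of 3460 genes (16.3%) differed by more than 2-fold. Libraries at 18 and 20 hpf correlated at 0.988 with 23 such genes, and 20 hpf correlated with the 24 hpf libraries at 0.974 (replicate 2, 125 genes) and 0.942 (replicate 3, 571 genes). Tk4 (5.69 against 72.3 CPM) and Nop9 (28.0 against 243) were higher in replicate 3, and PppL_270 (443 against 15.0), GagpolL_10, Nlr131 and Dach (141 against 9.56) in replicate 2. Of the differing genes 378 were higher in replicate 3 and 186 in replicate 2. No test was run on 2 libraries.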

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

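Of the tests in this part, the splits, the cell mix and the sets of libraries for even and odd hours, the step from 15 to 16 hpf, the depth of the 24 hpf pair and its comparison with those sets, both tests of the ribosomal rise and the splits of the 4 gene counts by stage were chosen only after the result was seen.

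Of 71 groups of library values searched for a value far from the others, 16 held one. Chance gives about 1 in 20 for independent values in random order, but the hours of a class follow development. Class shares also depend on one another, and a single value above 0 in a group is always flagged, so 16 is no measure of odd libraries. The library at 6 hpf stood apart from the other cleavage libraries by its 5584 cells (next 872), its 16222078 UMIs (next 4173971) and its ribosomal protein share of 0.7425% (next 0.581%). It also held the only cells of named classes in cleavage, with 1.21777% gut-like and 0.0179083% skeletogenic-like cells, 98.7643% unnamed cells against 100% elsewhere, and 0.14547% of cells over the Tbx2/3 gate. Endo16 at 12 hpf was the highest of the blastula at 315.887 CPM (next 116), as was the share of cells over its gate at 9.00357% (next 3.36%). Tbx2/3 at 13 hpf was the highest of the gastrula at 582.117 CPM (next 500), and Nanos2 at 7 hpf the highest of the blastula at 9.94332 CPM (next 4.31). The library at 7 hpf had the fewest skeletogenic-like cells of the blastula, 3.56447% (next 4.63%). The unnamed cluster 16, with 6 skeletogenic markers, is not in these shares. It held 376 cells at 6 hpf, 62 at 7 hpf, 27 at 8 hpf and fewer in the later blastula libraries. The low share at 7 hpf therefore depends on how that cluster is named. The library at 18 hpf had the most blastocoelar-like cells of the gastrula, 7.04399% (next 5.13%), and the one at 13 hpf the most unnamed cells, 4.59597% (next 2.16%). Cells with 2 or more UMIs of Nanos2 after thinning were 0.245399% at 5 hpf (next 0.0208%) and, by 1 cell, 0.0251446% at 14 hpf, against 0% in the other gastrula libraries. At 1 or more UMI, as in its gate test, the gastrula held 0.369% ± 0.159 (SD, n = 5).

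Seed genes were also above the limit that a count of 0 allows in libraries that their gate tests did not use. The highest such levels were 8.19344 CPM for Alx1 at 15 hpf (limit 0.983), 8.3853 for Pks1 at 3 hpf (0.719), 2.6403 for Endo16 at 5 hpf (0.99), 13.3465 for FoxQ2 at 4 hpf (1.21), 15.8418 for Tbx2/3 at 5 hpf (0.99) and 6.60075 for Nanos2 at 5 hpf (0.99).

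The difference between even and odd hours from 7 to 14 hpf was weighed first. Of 35 splits of the 8 libraries 1 passed as many genes, the real one with 3677 (highest other 1), but it was picked because it stood out, so this rank does not exclude chance. Unequal depth is argued against by a slope on the full difference of 0.932 with only cells of 2000 to 3000 UMIs kept (0.927 to 0.942 with each hour left out in turn), and an unequal mix of cell types by a slope of 0.967 (0.94 to 1.01 likewise) within the skeletogenic-like cluster 10, over 2011 of the genes. Whether libraries from 7 to 14 hpf were collected or handled as separate sets stays open, since the smaller of the slopes between the differences of 7 to 10 hpf and of 11 to 14 hpf, 0.724 (95% interval over resampled genes 0.696 to 0.754), is what any steady alternation would give. Sets that go on by even and odd hours after 14 hpf are argued against by a slope of 0.0697 (0.0538 to 0.0899) of the step from 15 to 16 hpf on the difference and of -0.593 (-0.628 to -0.563) from 16 to 18 hpf, both even, though the step from 14 to 15 hpf had -0.227 (-0.260 to -0.201), so which later libraries would belong to which set stays open, the labels give no batch, and no biological explanation was tested.

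The difference between the 2 libraries at 24 hpf was weighed next, where 564 genes differed by more than 2-fold. Cells of unequal depth are argued against by a slope of 1.00 (95% counting interval 0.988 to 1.04) with only cells of 2000 to 3000 UMIs kept, a test that took the place of leaving out cells under 1000 UMIs, which held only 10.5% and 18.6% of the UMIs. An unequal mix of cell types is argued against by a slope of 0.927 (0.907 to 0.965) within the dorsal-like cluster 3, although unnamed cells were 24.9% and 52.9% of the pair. If the pair came 1 from each of the sets of 7 to 14 hpf, its difference would follow theirs, but the slope was 0.148 (0.130 to 0.166). The labels give both libraries the same stage and time, so no biological explanation was tested, and separate embryos, handling or sequencing stay open as untested.

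The ribosomal protein rise from cleavage to blastula was weighed last. Its median log2 change was 2.22 over 82 members, 0 of which lacked UMIs in a class. Separate sets of even and odd hours are argued against as the cause by a median of 1.91 within odd and 2.43 within even hours, though within odd hours fry's adjusted p was 0.168 (0.0137 within even hours). Unequal depth is argued against by a median of 2.60 with only cells of 2000 to 3000 UMIs kept. By hour, these genes held 0.7425% of UMIs at 6 hpf, 0.729% at 7 hpf and 6.08% at 12 hpf. Between odd hours the share went from 0.525% at 5 hpf to 0.729% at 7 hpf. Most of the rise thus lay within the blastula hours and not at the border of the classes. A change with stage, which the design names, stays open as a gradual one over hours, with the call lost in camera (adjusted p = 0.517 with an estimated correlation).

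For each count by stage, at most 2 of the splits of the libraries, the real one among them, passed as many. The libraries follow one another in time, so any gradual change over hours also favours the real split. These ranks therefore speak only against a random arrangement of libraries, not for a change at the border of 2 classes. For all classes, 13227 genes passed against 4956 in the highest other of 60 splits, and 1 split, the real one, passed as many. From cleavage to blastula 10569 passed against 7738 (1 of 60, the highest other exchanging 6 and 7 hpf), from blastula to gastrula 3145 against 993 (1 of 60), and from gastrula to prism and larva 625 against 150 (1 of 56). For the lists, 20 passed fry from cleavage to blastula against 20 in 1 other split (2 of 60), 7 against 4 from blastula to gastrula (1 of 60), and 1 against 0 from gastrula to prism and larva (1 of 56). For the gates, gated and other cells were exchanged within libraries at random, and 1 of 21 draws, the real one, passed as many in each gate. The highest other was 652 for Alx1 (3290 in the real one) and 64 for Nanos2 (416). It was 0 for Pks1, Endo16, FoxQ2 and Tbx2/3 (5141, 6150, 2910 and 2972). A rank of 1 of 21 is the lowest these draws allow, and random exchange cancels any steady difference between gated and other cells. The ranks of the gates therefore speak only against a random exchange of gated and other cells. The Nanos2 count was 38 with matched cells, 38 in DESeq2 and 0 in edgeR with no replicate block. False calls were 20.5% in its simulation.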

How the results depend on the processing

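The fits within even or odd hours, with even or odd hour as a covariate, without 15 and 18 hpf, without cluster 14 or 17, with cells of 2000 to 3000 UMIs only or with gated cells of 1 cluster were chosen after seeing the data.

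Of the genes named by rule, 750 gene and setting pairs kept direction and call under the planned settings and 16 lost the call (5 from gastrula to prism and larva, 11 in the Tbx2/3 gate with no replicate block); with each library left out 1899 kept it and 45 lost it, and under the added settings 513 and 105. None reversed. These genes were chosen for not overlapping between classes or for being higher in every library, so fewer libraries could hardly reverse them. For the stage contrasts the libraries left out also include those of other classes. Of counts and shares, 90 stayed within 1.5 times or 1 SD under the planned settings and 42 moved, 286 and 28 with a library left out, and 38 and 41 under the added settings. Thinned libraries held fewer UMIs and fits within even or odd hours had fewer libraries; for other changes the cause was not tested. Gates of 3 or more UMIs gave no value for Alx1 and Nanos2. DESeq2 gave no adjusted p for 452 genes over all classes and 60 in each contrast, and for 11727 in the Nanos2 gate. No pairing of the stage classes was possible because the labels do not link their libraries and the replicate numbers only follow the hours.

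With libraries thinned to the shallowest, 8634 genes passed over all classes, 1957 from blastula to gastrula and 166 from gastrula to prism and larva, where DESeq2 passed 969. With cells of 2000 to 3000 UMIs, 6814 passed from cleavage to blastula and 359 from gastrula to prism and larva. With even or odd hour as a covariate, 12977 passed over all classes and 10651, 2928 and 448 in the 3 contrasts. Within even hours 8401 passed over all classes and 6337, 386 and 65 in the 3 contrasts; within odd hours 5991 over all classes, 5763 from cleavage to blastula and, in edgeR, 0 from blastula to gastrula, with 2563 at an unadjusted p under 0.05. Without 15 and 18 hpf, 703 passed from blastula to gastrula. Within even hours without 18 hpf, 7594 passed over all classes and 5959, 43 and 55 in the 3 contrasts, and within odd hours without 15 hpf, where the lone gastrula library is assumed to vary like the other groups, 1517 over all classes, 3598 from cleavage to blastula and, in edgeR, 0 from blastula to gastrula (706 unadjusted).

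Of the 24 lists, camera passed 0 in each contrast (2, 0 and 1 at an unadjusted p under 0.05) where fry passed 20, 7 and 1. With RLE size factors fry passed 12 from blastula to gastrula and 2 from gastrula to prism and larva. With even or odd hour as a covariate it passed 21, 7 and 1 in the 3 contrasts. Within odd hours it passed 7 from cleavage to blastula and 0 from blastula to gastrula (2 unadjusted), within even hours 0 from blastula to gastrula and 0 from gastrula to prism and larva (6 and 2 unadjusted). From blastula to gastrula it passed 0 without 15 and 18 hpf (7 unadjusted), 0 within even hours without 18 hpf (3) and 0 within odd hours without 15 hpf (0). From cleavage to blastula it passed 1 within odd hours without 15 hpf (10 unadjusted), and from gastrula to prism and larva 0 within even hours without 18 hpf (2). From gastrula to prism and larva it passed 0 without cluster 14 (4 unadjusted) and 0 with cells of 2000 to 3000 UMIs (3 unadjusted).

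With no replicate block, the gates passed 1548 genes for Alx1, 3618 for Endo16, 939 for FoxQ2, 57 for Tbx2/3 and 0 for Nanos2 in edgeR (819 at an unadjusted p under 0.05). The library as a block takes up differences between hours. With no filter on low counts more genes were tested, and 5390 passed for Alx1 and 5280 for FoxQ2. For Nanos2, DESeq2 passed 38, RLE 158 and cells matched by UMI total 38. Within even hours the gates passed 2034 for Alx1, 1749 for Tbx2/3 and 105 for Nanos2, and within odd hours 1416 for Alx1, 3267 for Pks1, 3415 for Endo16, 1130 for FoxQ2 and 895 for Tbx2/3. Slopes passed for 1115 and 1098 genes in Alx1 cells and 1530 and 1457 in Pks1 cells within even and odd hours, and for 1501 in Pks1 cells of cluster 12.

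At 1 or more UMI after thinning, gastrula gate shares were 0.728% for Alx1, 9.12% for Pks1, 23.5% for Endo16, 8.75% for FoxQ2, 35.0% for Tbx2/3 and 0.369% for Nanos2. At 2 or more UMIs without thinning they were 0.249% for Alx1, 7.38% for FoxQ2, 30.4% for Tbx2/3 and 0.0411% for Nanos2. For gastrula class shares, 4000 variable genes gave 2.89% apical-like, 4.27% blastocoelar-like and 34.8% ventral-like cells. Without the top 1% of cells by UMIs, clustering gave 14.7% apical-like, 3.83% blastocoelar-like, 20.2% dorsal-like, 23.6% gut-like and 0% ventral-like cells. Resolution 0.5 gave 0% blastocoelar-like and 0% pigment-like cells, and resolution 2 gave 31.4% dorsal-like and 23.0% ventral-like cells. Above 10 CPM, 1745 genes differed by more than 2-fold at 24 hpf.

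With each library left out in turn, counts ranged from 12307 to 13747 over all classes, 9392 to 11434 from cleavage to blastula, 1887 to 4167 from blastula to gastrula and 159 to 937 from gastrula to prism and larva, and lists from 19 to 22, 5 to 14 and 0 to 3. Gates ranged from 2824 to 3975 for Alx1, 4562 to 5231 for Pks1, 5494 to 6436 for Endo16, 2634 to 3133 for FoxQ2, 2519 to 3077 for Tbx2/3 and 263 to 636 for Nanos2, and slopes from 2091 to 2651 for Alx1 and 2118 to 2925 for Pks1. Class shares ranged from 30.9% to 32.8% (ventral-like), 21.8% to 22.7% (dorsal-like), 20.5% to 21.3% (gut-like), 8.12% to 8.65% (pigment-like), 5.01% to 5.56% (blastocoelar-like), 4.57% to 4.79% (apical-like) and 4.18% to 4.42% (skeletogenic-like). Gate shares ranged from 0.0282% to 0.0666% for Alx1, 7.43% to 8.00% for Pks1, 17% to 19.9% for Endo16, 5.08% to 5.54% for FoxQ2, 15.6% to 16.6% for Tbx2/3 and 0% to 0.00629% for Nanos2.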

Other observations

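The overlaps with the authors' table and the lists for even and odd hours in this part were examined only after the main results had been seen.

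Members of further lists rose or fell from cleavage to blastula. So did 56.7% of all 18642 gene models tested, with 5900 up and 4669 down, and the counts are to be read against that share. Of 59 skeletal matrix members 33 rose (33 adjusted over the list alone; adjusted p = 0.390 with an estimated correlation). Of 11 ciliary band members 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.390 with an estimated correlation), with the tubulin Btub3 at 2.45 ± 0.41 (SE) on the log2 scale, and of 68 cilia members 22 rose and 9 fell (19 and 6; adjusted p = 0.692 with an estimated correlation), with the dynein heavy chain Dnahc8 at 2.61 ± 0.37. Of 111 immune and complement members 34 rose and 16 fell (31 and 15; adjusted p = 0.783 with an estimated correlation), among them the scavenger receptor Srcr143 (7.00 ± 0.82) and the Toll-like receptor Tlr034 (-3.19 ± 0.33). Of 37 heat shock and stress members 14 rose and 9 fell (14 and 9; adjusted p = 0.797 with an estimated correlation), with Hsp701A at 1.81 ± 0.35 and Hsp40B at -3.52 ± 0.37. That call was lost without cleavage replicate 1 or 2 or blastula replicate 6 (fry adjusted p = 0.0662, 0.0734 and 0.0668). Of 15 pigment and flavin enzymes 6 rose and 2 fell (6 and 2; adjusted p = 0.537), of 10 hatching and blastula secreted members 4 rose (3; adjusted p = 0.517), and of 15 neural members 5 rose and 1 fell (4 and 1; adjusted p = 0.71), each p with an estimated correlation. These 8 lists passed fry, which does not compare members with the other genes, and 0 passed in camera, which does.

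The remaining 4 lists did not pass fry from cleavage to blastula. Of 103 neural function members 27 rose and 18 fell (24 and 17 adjusted over the list alone; fry adjusted p = 0.0616), such as Chrna6L (3.74 ± 0.58) and Syt9 (-4.93 ± 0.59). Of 16 egg and cortical granule members 4 rose and 4 fell (4 and 4; 0.631), of 13 germline members 3 rose, including Vasa (2.16 ± 0.49), and 4 fell (3 and 4; 0.488), and of 20 gut digestion members 5 rose and 3 fell (4 and 3; 0.241). From blastula to gastrula the ciliary band list had a median of -0.39 but a mean of 0.08, with 2 of 11 members rising and no call (fry adjusted p = 0.717).

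Genes higher by more than 2-fold in the gates overlapped with the clusters of the authors' deposited table, which was made from the same cells and is therefore not independent. Counting in each case only genes tested in the gate concerned, the authors' deposited table gives 401 genes for its cluster PMC3. Of these, 310 were among the 750 of the Alx1 gate, against 26.3 for independent lists, and 12 of the 12 genes named for that gate were in it. For its clusters PMC2 and PMC1 these were 212 of 293 and 56 of 267 (19.2 and 17.5 for independent lists), while NSM2, NSM_Blasto2 and NSM_Blasto1 shared 73, 84 and 64 (21.8, 26.6 and 20.3), an excess like that of PMC1 in ratio (3.34, 3.16 and 3.16 against 3.20). For NSM_Pigment 336 of 370 were in the Pks1 gate (34.6), and 12 of 12 named genes, and for NSM2 248 of 332 (31.1). For Endo4 73 of 250 were in the Endo16 gate (7.75), with 9 of its 12 named genes, for N_Gut 67 of 158 (4.90; 6 of 12), for NSM_Blasto1 56 of 309 (9.58; 2 of 12) and for Stomodeum 49 of 195 (6.05; 10 of 12). For Ecto_APD3 61 of 141 were in the FoxQ2 gate (2.13; 8 of 12), and for Ecto_AB5 7 of 225 in the Tbx2/3 gate (0.408; 5 of 12), with 5 of 344 for LCP (0.624; 0 of 12).

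Between even and odd hours from 7 to 14 hpf, the immune and complement list was the only one of 24 to pass fry (adjusted p = 0.0427), with 15 of 92 members higher in even and 4 higher in odd hours. Of all 17202 gene models tested 21.4% differed, 1990 higher in even and 1687 in odd hours, and fry does not compare members with the other genes. Of 81 ribosomal protein genes 20 were higher in even and 0 in odd hours, such as Rps19 (1.27 ± 0.16), without passing (fry adjusted p = 0.177). The other genes with large differences, chosen after their values were seen, included Atub13 (2545 against 1042 CPM) and Tgif (1.26 ± 0.19), higher in even hours, and EhH4_79 (-2.35 ± 0.14) and Myt1_1 (-1.93 ± 0.12), higher in odd hours.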
